A study of Mus musculus domesticus and Mus spretus and Mus musculus domesticus x Mus spretus with 44 samples.

How the data were processed

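The authors trimmed reads of 150 bp with Trim Galore 0.4.5, aligned them with HISAT2 2.1, sorted them with SAMtools 0.1.19, assembled and measured transcripts with StringTie 1.3.3 and tested them with DESeq2 1.16.1. The authors deposited count tables, which hold expected counts, that is whole-number estimated counts per gene that had not been normalized. How the authors turned transcript coverage into counts is not stated, the values peak at multiples of 4, and library totals are nearly constant. The authors also deposited a signal table per comparison, in normalized counts, that is the counts divided by 1 size factor per library. Per the file headers, the test tables of the authors hold a log2 fold change per gene in log2 units. Per the file headers, the same tables hold an adjusted p-value per gene, and the design formula behind it is not stated.

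Placental counts stood on GRCm38 with 50510 loci, of which 41901 had a gene name, 15113 of them through the gene names of other tables and GENCODE M21. Preoptic counts of domesticus dams stood on the WSB/EiJ annotation (37950 loci) and those of spretus dams on the SPRET/EiJ annotation (37080 loci). The species were joined over 17497 of the 17521 gene pairs in the table of the authors, and the joint comparison used the raw counts of both annotations, so its folds include differences between gene models. Loci without a name held 1.37% to 1.99% of the counts in placenta and 2.55% to 2.72% in the preoptic area.

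Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after its default filter on low counts and TMM scaling, with Benjamini-Hochberg adjustment over all tested genes and calls at adjusted p under 0.05. All 29 placentas were in 1 fit of 6 groups of type and sex, and a type contrast was the mean of the female and the male contrast (19743 genes). The mean of the parents was that of their log2 values. Libraries rather than litters were the units of that fit, with 1 female and 1 male placenta from each litter but the male-only hybrid litter 20. Domesticus dams were fitted alone (18289 genes), and spretus dams were compared in a fit of all 15 dams (14071 genes). A gene was called outside both parents when the hybrid differed from DOM and from SPRET in the same direction with both adjusted p under 0.05. Because both contrasts share the hybrid libraries, the overlap was set beside 10 simulated data sets and beside contrasts on separate hybrid litters. All gene tests and fold changes were two-sided, and CPM gives counts per M counts of the scaled library.

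The gene lists were written before the data were examined, 36 for placenta and 29 for the preoptic area, together with a list of all X-linked genes. They cover placental gene families, imprinted genes, placental, immune and neighbouring cell types, metabolic and stress pathways, maternal behaviour, neurotransmitter and steroid signalling, and neurons of neighbouring brain regions. A list was tested with camera of limma 3.58.1 on log2 CPM where at least 3 members were tested, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of the tissue, two-sided. Each was tested again with the correlation between members estimated. Counts of members are those called over all genes, and the adjustment over the list alone is given where its count differs.

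Genes were named by a rule written with the lists. It takes the 8 called genes with the largest rise and the 8 with the largest fall among named genes with a mean of at least 5 CPM in the higher group and no overlap of libraries between the groups. For sex it takes 4 autosomal genes per direction and the called sex-linked genes, and where under 10 genes were called it takes all of these and the 5 with the smallest p not called. From each list it takes up to 2 called members per direction, and some genes stand always, such as Prl3b1, Tpbpa, Igf2, Xist, Oxt, Esr1 and the dopamine receptors. Not all genes that the rule took are printed. Fold changes against a group with all libraries at 0 are not printed.

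Weights were averaged per litter, and litter means were compared with exact two-sided permutation tests of all 252 arrangements, or with exact two-sided sign-flip tests within litters for sex. Adjusted p covers the 12 weight tests. Values after ± are SD for weights and CPM and standard errors for log2 fold changes. Standard errors from the counts cover counting error and the variation between libraries, not errors of alignment or annotation.

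Alternatives written before the data were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, counts summed per litter, limma voom with litter as a random effect, 1 sex alone, only the 2 types compared, litter as a block for the sex results, and leaving out each litter. Alternatives added later were counts divided by 4, a yolk sac marker score as a covariate, leaving out the 10 placentas with a score over 1, a striatal and septal score as a covariate, and leaving out the hybrid-carrying dams of litters 11 and 20. Litters were paired as the labels state. After removal of the group means, 14 pairs of littermates had a median correlation of 0.107 over genes, against -0.028 in 56 female and male pairs of different litters. In the voom fit the correlation between littermates within a gene, estimated over all genes, was 0.217.

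The pipeline was tested on simulated data in which 200 genes were changed 1.5-fold, 2-fold or 4-fold. Simulated libraries were drawn independently, so these data held no effect of the litter. In HYBRID against DOM it recovered 52.2%, 86.6% and 98.5% of them, and 9.7% of the calls were false. In the sexes of DOM it recovered 37.3%, 70.1% and 89.4% with 7.1% false, and in the domesticus dams 20.9%, 83.6% and 97.0% with 9.5% false. Group labels were also rearranged in 60 splits per comparison, or 100 for the domesticus dams. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the other tables and the figures. Reads were not analysed here, so allele-specific expression was not measured.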

Results

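The series covered late mouse pregnancies of 3 types. Mus musculus domesticus dams carried domesticus litters (DOM), domesticus dams carried litters sired by Mus spretus (HYBRID placentas, DOMhl dams), and Mus spretus dams carried spretus litters (SPRET). Placentas freed of decidua came from 5 females and 5 males of DOM, 4 females and 5 males of HYBRID and 5 females and 5 males of SPRET, and the medial preoptic area (MPA), a brain region of maternal behaviour, came from 5 dams of each type. Library totals had medians of 64.7 M counts in DOM, 64.0 M in HYBRID and 64.1 M in SPRET placentas, and of 55.8, 55.7 and 55.2 M in the MPA of DOM, DOMhl and SPRET dams. In placenta the first principal component held 60.3% of the variance and the second 9.3%. Alpha fetoprotein (Afp), a yolk sac endoderm gene, ranged from 20.6 to 12510 CPM between placentas, with a mean of 3138 ± 3886 in DOM (n = 10), 4109 ± 4914 in HYBRID (n = 9) and 609.6 ± 1030 in SPRET (n = 10).

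Hybrid placentas were the lightest of the 3 types, and the embryos they carried were not. Hybrid placentas weighed 0.0352 ± 0.00557 g (mean and SD of 5 litter means), DOM placentas 0.0531 ± 0.00567 g and SPRET placentas 0.0504 ± 0.00535 g. HYBRID minus DOM was -0.0179 g (-33.7%), with no overlap of litter means (exact two-sided permutation p = 0.00794, the smallest that 5 litters against 5 can give, adjusted p = 0.0476). HYBRID minus SPRET was -0.0152 g (-30.1%, exact p = 0.0159, adjusted p = 0.0476), and SPRET minus DOM was -0.00275 g (exact p = 0.476). Embryos weighed 0.733 ± 0.195 g in HYBRID, 0.665 ± 0.0507 g in DOM and 0.570 ± 0.114 g in SPRET (exact p = 0.444 against DOM, 0.167 against SPRET and 0.127 between the parents). Without SPRET 13 the SPRET and DOM embryos differed by -0.133 g (exact p = 0.0476). HYBRID minus DOM embryo weight was 0.0685 g, and 0.00913 g without HYBRID 20, a male-only litter with 1 sampled embryo. The placenta made up 5.07 ± 0.993% of embryo weight in HYBRID, 8.06 ± 1.13% in DOM and 9.21 ± 2.30% in SPRET. HYBRID minus DOM was -2.99 percentage points (exact p = 0.00794, adjusted p = 0.0476), HYBRID minus SPRET was -4.14 (exact p = 0.0159, adjusted p = 0.0476) and SPRET minus DOM 1.15 (exact p = 0.333). Among female embryos alone the weight difference to SPRET was -0.0101 g (exact p = 0.0714), and the share of embryo weight differed by -1.65 from DOM (exact p = 0.0873) and by -2.52 from SPRET (exact p = 0.0794). Litters held 4.6 ± 1.14 HYBRID, 5.2 ± 0.837 DOM and 5.2 ± 0.447 SPRET pups (exact p = 0.556, 0.516 and 1).

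**Figure D1:**
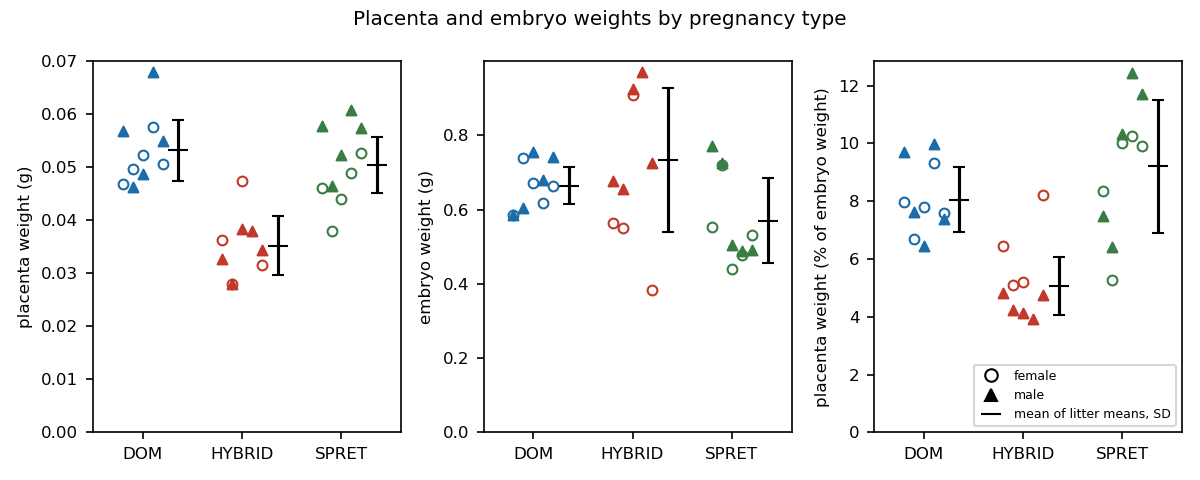
Placenta weight (g), embryo weight (g) and placenta weight as percent of embryo weight by pregnancy type, with points for single females and males and bars for the mean and SD of the 5 litter means. Hybrid placentas weighed 0.0352 g against 0.0531 g in DOM and 0.0504 g in SPRET.

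Within litters, male embryos were heavier than females in 12 of 14 litters, by a mean of 0.0665 g (exact two-sided sign-flip p = 0.0385, adjusted p = 0.25). Male SPRET placentas outweighed female ones in 5 of 5 litters (0.0549 g against 0.0459 g, difference 0.00906 g, exact p = 0.0625, the smallest possible, adjusted p = 0.25). In HYBRID the placenta was a smaller share of embryo weight in males in 4 of 4 litters (4.49% against 6.24%, difference -1.75, exact p = 0.125, the smallest possible).

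The neuropeptide gene galanin was higher and the placental cathepsin Cts7 lower in HYBRID than in DOM placentas. Gal rose 51.0-fold, from 0.864 CPM in DOM (n = 10) to 40.4 CPM in HYBRID (n = 9), a log2 fold change of 5.67 ± 0.39, and stood at 108 CPM in SPRET. Cntn2, a neural cell adhesion gene, rose 39.8-fold (log2 5.32 ± 0.36) and Cidea, a lipid droplet gene, 36.9-fold (5.21 ± 0.30). Further large rises were in Elfn1 (4.64 ± 0.51), Bdh2 (4.58 ± 0.30), Doc2b (4.40 ± 0.32), the podocyte gene Nphs1 (4.30 ± 0.53) and the meiosis gene Sycp1 (4.29 ± 0.42). Large falls without overlap of libraries were in Thsd7b (-5.47 ± 0.41), the placental cathepsin Cts7 (-4.86 ± 0.36, from 150 to 5.45 CPM, with 0.0723 CPM in SPRET), the opioid-like precursor Pnoc (-4.79 ± 0.57) and Prl3d1, placental lactogen I (-3.67 ± 0.37, from 68.3 to 5.65 CPM, with 0.126 CPM in SPRET). Zfp575 (-3.07), Gal3st3 (-2.59), Prom2 (-2.25) and Sel1l3 (-2.23) also fell. Gal lies on GRCm38 chromosome 19 from 3409915 to 3414544 (ENSMUSG00000024907) and Cts7 on chromosome 13 from 61352461 to 61358197 (ENSMUSG00000021440).

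Of 25 tested genes of the placental prolactin family, hormones of the trophoblast, 13 fell and none rose (median log2 -0.81, camera adjusted p = 0.000933, but adjusted p = 0.836 with an estimated correlation). Prl3b1, placental lactogen II, fell 2.20-fold, from 17770 ± 2778 to 8116 ± 1311 CPM (log2 -1.14 ± 0.14, edgeR adjusted p = 3.18e-07), and stood at 6079 CPM in SPRET. It lies on GRCm38 chromosome 13 from 27241847 to 27249683 (ENSMUSG00000038891), and Prl3c1 fell too (-1.79 ± 0.29). All 7 placental cathepsins fell (median -0.97, adjusted p = 0.000327, but adjusted p = 0.638 with an estimated correlation), among them Ctsm (-1.10). Among 11 Ceacam genes 2 rose and 4 fell, with Ceacam3 up by 3.13 ± 0.26 (17.2 to 164 CPM, SPRET 583) and Ceacam5 down by -1.65 ± 0.23 (1335 to 441 CPM, SPRET 84.2). Among 13 pregnancy-specific glycoproteins 2 rose and 6 fell, with Psg22 up (2.45 ± 0.24) and Psg26 (-1.18) and Psg27 (-1.09) down (adjusted p = 0.884). Counts within these families of close paralogs depend on how reads were shared between copies.

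Markers of the junctional zone fell in part. Of 11 spongiotrophoblast genes 1 rose and 4 fell (median -0.43, adjusted p = 0.0485, but adjusted p = 0.836 with an estimated correlation). That call was lost without any 1 of HYBRID 10 (adjusted p = 0.0735), HYBRID 20 (0.0959), DOM 16 (0.0560), DOM 18 (0.0725), DOM 21 (0.0689), DOM 8 (0.0829), SPRET 13 (0.0538) or SPRET 6 (0.0514). Tpbpa, its best known marker, fell by 0.68 ± 0.20 (3543 to 2295 CPM, adjusted p = 0.00897). Of 14 glycogen trophoblast genes 2 rose and 7 fell, with Aldh1a3 (-2.45 ± 0.45) and Plac8 (-1.24 ± 0.20) lower, and of 12 giant cell genes 2 rose and 5 fell (camera adjusted p = 0.171 and 0.223). Among 15 syncytiotrophoblast genes 2 rose and 1 fell, among 14 of fetal endothelium 4 and 2, among 14 of stroma 6 and 2, and among 14 of maternal decidua 1 and 1. None of 15 yolk sac endoderm genes was called.

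Of 27 maternally expressed imprinted genes 10 rose and 2 fell (adjusted p = 0.245): Phlda2, a brake on placental growth, rose by 1.01 ± 0.21 (6.86 to 14.2 CPM, SPRET 6.41) and Ascl2, needed for spongiotrophoblast, fell by 1.15 ± 0.30. H19 (0.18, adjusted p = 0.161) and Cdkn1c (0.20, adjusted p = 0.118) were not called, although H19 was without DOM 8 (0.26, adjusted p = 0.0368). Of 23 paternally expressed genes 5 rose and 4 fell (adjusted p = 0.884). The growth factor Igf2 rose by 1.12 ± 0.37 (2307 to 4992 CPM, adjusted p = 0.0186), a call lost without HYBRID 10 (0.87, adjusted p = 0.0986) or HYBRID 11 (1.03, adjusted p = 0.0545).

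Of 31 interferon response genes 14 rose and none fell (15 and 1 adjusted over the list alone), with Mx1, an antiviral GTPase, up by 4.10 ± 0.38 and Gbp3 by 2.25 ± 0.19. The list passed (median 0.28, adjusted p = 0.0224, but adjusted p = 0.84 with an estimated correlation) but not without DOM 16 (adjusted p = 0.0567). Of 18 genes of MHC class I 9 rose and 1 fell (10 and 2 over the list alone, adjusted p = 0.425), with H2-D1 up by 1.27 ± 0.18. Of 15 erythroid genes 6 fell, among them Epb42 (-1.54) and Ermap (-1.28) (median -0.71, adjusted p = 0.0285, but adjusted p = 0.856 with an estimated correlation, and 0.0596 without DOM 21). Of 12 genes of the X-linked Rhox cluster 5 fell (median -0.28, adjusted p = 0.0224, but adjusted p = 0.638 with an estimated correlation), with Rhox9 down by -0.72 ± 0.08. Of 34 ribosomal protein genes 12 fell, by a median of -0.19 (adjusted p = 0.0148, but adjusted p = 0.987 with an estimated correlation), among them Rps15 (-0.84). The list of steroid synthesis held 2 risen and 8 fallen of 19, with Cyp17a1, the enzyme of androgen synthesis, up by 0.98 ± 0.13 and Hsd17b2 down by -1.01 ± 0.12 (adjusted p = 0.128).

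No set test passed for the other lists, and their risen and fallen members follow. Nutrient transporters gave 8 and 5 of 29, with Slc2a3, a glucose transporter, up by 0.78 ± 0.18. Hypoxia response gave 3 and 5 of 27, cell cycle 2 and 6 of 34, endoreduplication 3 and 2 of 13, cholesterol synthesis 4 and 5 of 18, angiogenic factors 5 and 2 of 19, and heat shock 2 and 3 of 25. Angiogenic Pgf rose by 1.03 ± 0.23 and Angptl4 fell by 1.21. Macrophages gave 0 and 1 of 14, uterine NK cells 0 and 1 of 13, neutrophils 2 and 4 of 10, cytokines 2 and 3 of 24, histones 0 and 2 of 8, X-linked growth genes 3 and 3 of 14 and all X-linked genes 100 and 53 of 602. No mitochondrial gene of 10 and no Y-linked gene of 5 was called.

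Altogether 6475 of 19743 genes (32.8%) were called between HYBRID and DOM placentas, 3496 higher and 2979 lower in HYBRID, 1942 of them over 2-fold. Females alone gave 2652 and males alone 3885, and leaving out the 10 placentas high in yolk sac markers gave 3801. Of the genes named above, Phlda2 (adjusted p = 0.0883), Ascl2 (0.316), Epb42 (0.0716), Cyp17a1 (0.264), Angptl4 (0.157) and Igf2 (0.101) were not called in females alone, and Tpbpa (0.717), Psg26 (0.371), Psg27 (0.377), Ctsm (0.398) and Igf2 (0.168) not in males alone. Without the placentas high in yolk sac markers Igf2 (0.0566), Tpbpa (0.127), Ctsm (0.103), the spongiotrophoblast list (0.0675) and the erythroid list (0.0571) did not pass.

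**Figure D2:**
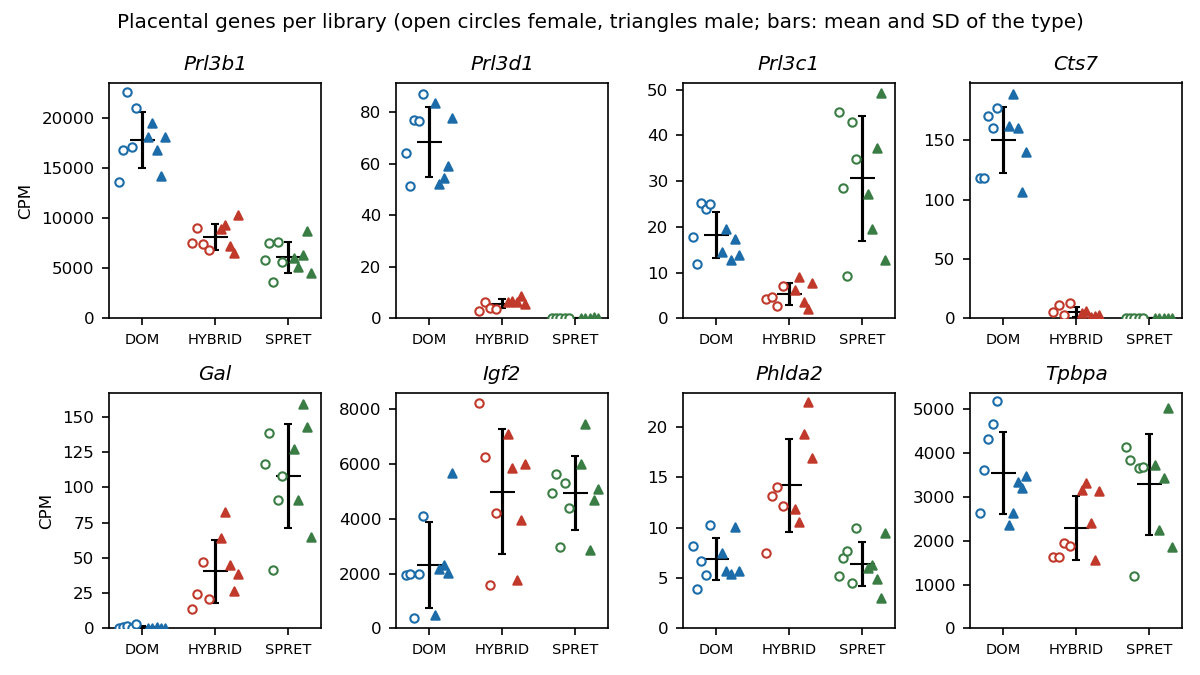
Expression of 8 placental genes in CPM (vertical axis) by pregnancy type, with 1 point per placenta (open circles female, triangles male) and bars for the mean and SD of the type. Prl3b1 had means of 17770 CPM in DOM, 8116 in HYBRID and 6079 in SPRET, and Phlda2 of 6.86, 14.2 and 6.41.

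HYBRID placentas differed from SPRET placentas in hormones, blood and immune genes. The macrophage and lymphatic gene Lyve1 stood at 21.1 CPM in HYBRID (n = 9) and 0.828 in SPRET (n = 10), log2 4.69 ± 0.20, and Cd163 was higher too (4.26). H2-K1 (9.43 ± 0.31, 160 against 0.234 CPM) and Abcc12 (9.92 ± 0.39) were near 0 in SPRET, as was mt-Co2 (16.2 against 0.0147 CPM), and Lncenc1 (18.7 CPM) and Khdc1c (5.54 CPM) had no counts there. Placental reads of all types stood on GRCm38, so low SPRET counts of these genes, and of lists lower in SPRET, may in part be lost spretus reads. Large falls without overlap of libraries were in Inmt (-10.46 ± 0.99), the prostaglandin D synthase Ptgds (-9.23 ± 0.81, 0.639 against 372 CPM), Tmem45a (-5.25), Atp2b3 (-4.51), the immune checkpoint ligand Cd274 (-4.19 ± 0.18, 6.96 against 127 CPM), Fibcd1 (-4.17) and Htr6 (-4.10).

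Of 25 prolactin family genes 2 were higher and 16 lower in HYBRID than in SPRET (median -1.17, adjusted p = 0.00119, but adjusted p = 0.688 with an estimated correlation). Prl3c1 was lower (-2.56 ± 0.30), Prl3d1 higher (5.43) and Prl3b1 higher by 0.41 (adjusted p = 0.0156, but 0.0639 without HYBRID 11, 0.242 in females alone and 0.142 without the placentas high in yolk sac markers). Pregnancy-specific glycoproteins had 9 of 13 lower and none higher (median -1.16, adjusted p = 0.00101, but adjusted p = 0.688 with an estimated correlation), with Psg20 (-2.45) and Psg22 (-2.38). Genes of MHC class I had 15 of 18 higher (median 0.92, adjusted p = 2.22e-11, but adjusted p = 0.0632 with an estimated correlation). Erythroid genes had 11 of 15 higher (median 1.48, adjusted p = 0.00557, but adjusted p = 0.688 with an estimated correlation), with Epb42 (1.82, but adjusted p = 0.0519 in males alone) and Tspo2 (1.81). Macrophage genes had 8 of 14 higher and 2 lower (median 1.07, adjusted p = 0.018, but adjusted p = 0.688 with an estimated correlation, and 0.0600 without SPRET 14). Cell cycle genes had 16 of 34 lower and 1 higher (median -0.47, adjusted p = 0.00563, but adjusted p = 0.832 with an estimated correlation), with Bub1b (-1.94). Heat shock genes had 12 of 25 lower and 3 higher (median -0.32, adjusted p = 0.0135, but adjusted p = 0.688 with an estimated correlation). Rhox genes had 7 of 12 higher and 1 lower (median 0.47, adjusted p = 0.00557, but adjusted p = 0.24 with an estimated correlation). Mitochondrial genes had 7 of 10 higher and 2 lower (median 2.54, adjusted p = 1.48e-05, but adjusted p = 0.45 with an estimated correlation). Beside these groups, 9 of 15 yolk sac endoderm genes were higher in HYBRID (median 2.31, adjusted p = 0.159, and 0.0200 without SPRET 7), among them Cubn (3.85). Igf2 did not differ (0.02, adjusted p = 0.971), and Slc2a3 was higher by 2.09 ± 0.18. In all 9007 genes (45.6%) were called, 4968 higher and 4039 lower, and females alone gave 4352.

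The parents differed from each other in more genes than the hybrid did from either. SPRET exceeded DOM in Ptgds (10.46 ± 0.80), Inmt (8.16), the neurotrophin receptor Ngfr (7.45), Gal (7.21 ± 0.41), Cntn2 (6.71), Alox12e (6.70), Dpysl5 (6.49) and Apoa5 (6.28), n = 10 each. DOM exceeded SPRET in Cts7 (150 against 0.0723 CPM), H2-K1 (229 against 0.234 CPM, log2 -9.94 ± 0.31) and Prl3d1 (-9.09). Spretus reads lost on GRCm38 may contribute here too, and to the lists lower in SPRET. Of 25 prolactin family genes 11 were higher in SPRET and 4 lower, with Prl8a1 up (2.59, 73.1 to 441 CPM) and Prl3b1 down (-1.55), and the family had a positive median (0.62) and a negative mean (-0.22) and did not pass (adjusted p = 0.922). Pregnancy-specific glycoproteins had 8 of 13 higher and 3 lower (adjusted p = 0.178, and 0.0311 without SPRET 14), with Psg22 (4.83 ± 0.26), and Ceacam genes 6 of 11 higher and 2 lower, with Ceacam3 (5.10) and Ceacam5 (-3.97). Erythroid genes had 13 of 15 lower in SPRET (median -2.02, adjusted p = 0.00184, but adjusted p = 0.994 with an estimated correlation). MHC class I genes had 11 of 18 lower and 1 higher (median -0.86, adjusted p = 0.000758, but adjusted p = 0.784 with an estimated correlation). Rhox genes had 9 of 12 lower (median -1.16, adjusted p = 0.00107, but adjusted p = 0.221 with an estimated correlation). Mitochondrial genes had 3 of 10 higher and 7 lower (median -2.47, adjusted p = 0.0184, but adjusted p = 0.994 with an estimated correlation, and 0.0598 without SPRET 14). Beside these, 8 of 15 yolk sac endoderm genes were lower in SPRET. Altogether 12200 genes (61.8%) were called, 5854 higher and 6346 lower in SPRET.

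Some genes of the hybrid placenta lay outside both parents. Above both stood Rhbdl3 (log2 2.18 ± 0.19 over DOM and 2.07 ± 0.19 over SPRET), the uroplakin Upk1b (2.49 ± 0.20 and 1.51 ± 0.19, with 6.66, 37.4 and 13.2 CPM in DOM, HYBRID and SPRET), the collagen Col4a5 (1.47 and 1.20), cyclin D1 (Ccnd1, 0.82 and 1.58), the Hedgehog transducer Smo (0.65 and 1.24), Txlng (0.74 and 0.92), Nr6a1 (0.60 and 0.85) and the retinol dehydrogenase Rdh10 (0.85 and 0.54). Below both stood Prl3c1 (-1.79 ± 0.29 and -2.56 ± 0.30, with 18.2, 5.30 and 30.6 CPM), the netrin receptor Unc5a (-1.06 and -1.62), Tnfaip8l1 (-1.37 and -0.94), the galanin receptor Galr2 (-1.68 and -0.76), Fhl3, Man1a, Tmem108 and Prdx4. Prl3c1 lies on GRCm38 chromosome 13 from 27196659 to 27203749 (ENSMUSG00000017922).

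Of the 25 prolactin family genes 9 lay below both parents and none above, among them Prl7a1 (-1.05 and -2.04), Prl4a1 (-0.87 and -1.63), Prl7a2 (-0.85 and -1.91) and Prl2c5 (-0.93 and -1.34). Glycogen trophoblast genes had 5 of 14 below and none above, with Plac8 (-1.24 and -1.26) and Aldh1a3 (-2.45 and -1.79). Maternally expressed imprinted genes had 6 of 27 above and 1 below, with Phlda2 (1.01 and 1.11) above and Ascl2 (-1.15 and -1.40) below. MHC class I genes had 7 of 18 above, interferon response genes 3 of 31 above and fetal endothelium 4 of 14 above and 1 below. Of other genes, the insulin-like growth factor receptor Igf1r (0.48 and 0.32) and Gpc4 (0.94 and 0.68) lay above both, and Angptl4 (-1.21 and -0.68), the fatty acid carrier Mfsd2a (-0.58 and -1.56) and Tpbpa (-0.68 and -0.58) below, although Tpbpa was not called against SPRET without SPRET 6 (-0.47, adjusted p = 0.0596) or with litter as a random effect (0.0653).

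In all 980 genes (5% of 19743) lay outside both parents, 493 above and 487 below, and 2661 lay between parents, 1341 of them above DOM and 1320 below. Both contrasts share the hybrid libraries. Data simulated without differences gave 0 such genes, and data with the hybrid at the arithmetic mean of the parents gave a median of 17 and at most 22, whereas independent lists of the same size would share 1489. Contrasts on separate hybrid litters gave 409 and 416, against 793 and 756 for independent lists. In females alone Phlda2, Ascl2, Aldh1a3, Angptl4 and Mfsd2a were not called against at least 1 parent, and in males alone Tpbpa was called against neither. Females alone gave 176, males alone 582 and those low in yolk sac markers 466.

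**Figure D3:**
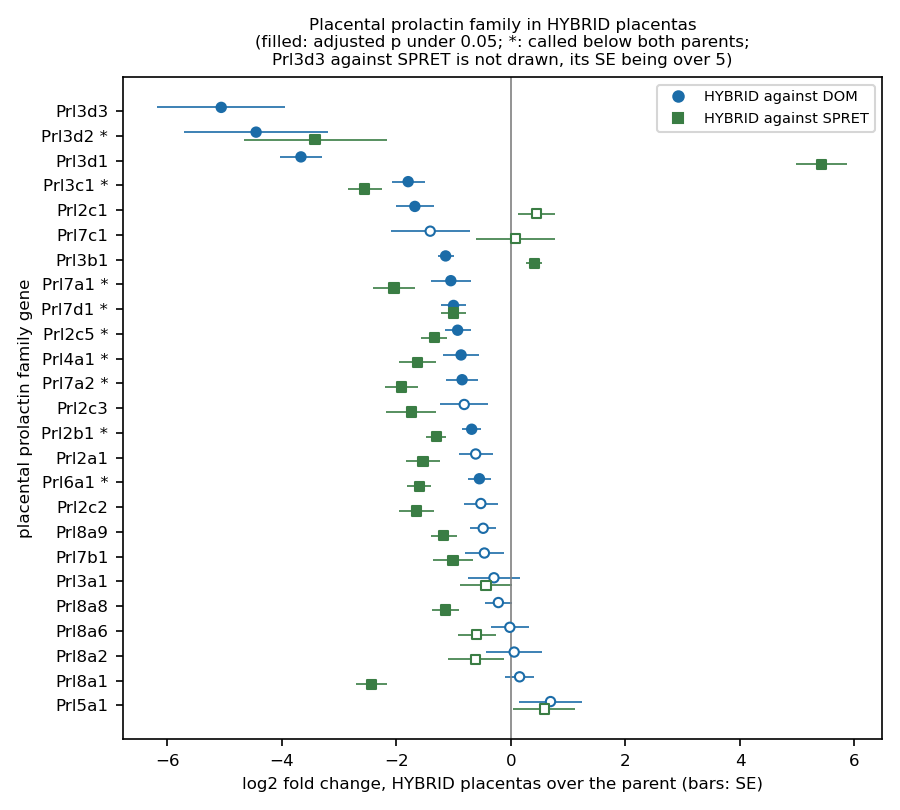
Log2 fold change of each placental prolactin family gene in HYBRID placentas over DOM and over SPRET, 1 point per contrast, filled where adjusted p was under 0.05, with bars for the standard error and stars for genes below both parents. Of the 25 genes 9 lay below both, such as Prl3c1 at -1.79 and -2.56.

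Against the mean of the log2 values of the parents the hybrid differed in 4736 genes, 3111 higher and 1625 lower. On that scale a hybrid at the arithmetic mean of unlike parents stands higher, and data simulated with it there gave a median of 1146 genes higher and 29.5 lower. Of the 3111 genes 2706 lay above the arithmetic mean of the parents too. Of the 1625 genes 1624 lay below it, nearly by construction, since it is never below the mean of the log2 values. Prolactin family genes had 16 of 25 lower and 1 higher (adjusted p = 4.41e-08, but adjusted p = 0.354 with an estimated correlation). Genes of MHC class I had 16 of 18 higher, all of them above the arithmetic mean too (median 0.71 on the log2 scale and 0.51 against the arithmetic mean, adjusted p = 2.27e-14, and adjusted p = 0.015 with an estimated correlation) and maternally expressed imprinted genes 14 of 27 higher and 3 lower (median 0.39, adjusted p = 0.00758, and adjusted p = 0.0408 with an estimated correlation). Glycogen trophoblast genes had 2 of 14 higher and 6 lower (adjusted p = 0.00619, but adjusted p = 0.143 with an estimated correlation), and pregnancy-specific glycoproteins 5 of 13 lower (adjusted p = 0.000444, but adjusted p = 0.56 with an estimated correlation). H2-K1, at 160 CPM against an arithmetic mean of 115 CPM, had 4.46 on the log2 scale and 0.48 against the arithmetic mean. The set tests were on the log2 scale alone. The hybrids had domesticus dams, so for maternally expressed imprinted genes DOM rather than the mean of the parents is the level to compare. Against DOM that list did not pass (camera adjusted p = 0.245). Single genes were Rhbdl3 (2.13) and Upk1b (2.00) above, and Prl3c1 (-2.17), Unc5a (-1.34), Galr2 (-1.22) and Tnfaip8l1 (-1.15) below. Females alone gave 1258 genes, males alone 2986 and those low in yolk sac markers 2409.

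Male and female placentas differed in 9 genes in DOM, 10 in HYBRID and 7 in SPRET, most of them sex-linked. Xist, the RNA of X inactivation, stood at 105 CPM in DOM females (n = 5) and 3.90 in males (log2 -4.75), at 62.6 and 3.13 in HYBRID (-4.32) and at 45.6 and 1.68 in SPRET (-4.77). The Y-linked genes Ddx3y (57.9, 56.7 and 62.2 CPM in DOM, HYBRID and SPRET males), Eif2s3y (28.5, 25.1 and 22.2), Uty and Kdm5d rose in males of each type, 4 of 5 listed Y-linked genes. The autosomal GTPase gene Rab12 was lower in SPRET males (67.9 to 20.7 CPM, log2 -1.72 ± 0.11, adjusted p = 4.84e-11) while females and males had 83.4 and 87.8 CPM in DOM and 69.8 and 74.8 in HYBRID. It lies on GRCm38 chromosome 17 from 66494512 to 66519729 (ENSMUSG00000023460). In HYBRID males the X-linked Gm14597 (3.11 to 0.696 CPM, -2.16 ± 0.21, adjusted p = 2.40e-07) and Fndc3c1 (15.7 to 7.42 CPM, -1.08 ± 0.15, adjusted p = 0.000208) fell. The androgen synthesis gene Cyp17a1 fell in DOM males (70.2 to 32.8 CPM, -1.10 ± 0.18, adjusted p = 0.00616), a call lost without DOM 16 (-0.97, adjusted p = 0.142) or DOM 8 (-0.99, adjusted p = 0.0981). Also called were Car11 in DOM males (-1.15, adjusted p = 0.0398) and, in HYBRID males, Kctd20 (-1.10, adjusted p = 0.0192) and the Notch ligand Dll4 (-0.77, adjusted p = 0.0344), and each lost its call with single litters left out. Not called in DOM with the next smallest p were Asns (-0.50) and Card14 (-1.38).

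With litter as a block 5, 3 and 3 genes were called in DOM, HYBRID and SPRET, and the calls of Cyp17a1 (adjusted p = 0.395), Car11 (0.774), Kctd20 (0.124), Dll4 (0.538), Gm14597 (0.134) and Fndc3c1 (0.231) were lost, while that of Rab12 held. The block also took the calls of Kdm5d and Uty in HYBRID (adjusted p = 0.231 and 0.124) and of Kdm5d, Uty and Xist in SPRET (each 0.0780). DESeq2 called 36 genes in DOM and 32 in SPRET. Without SPRET 14 the SPRET count was 17 in place of 7.

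The sex difference itself differed between the types for 3 genes. Rab12 had an interaction of -1.79 ± 0.16 in SPRET against DOM (adjusted p = 1.21e-07) and of 1.82 ± 0.16 in HYBRID against SPRET. Gm14597 had -2.47 ± 0.29 in HYBRID against DOM (adjusted p = 5.46e-05) and -2.14 ± 0.28 against SPRET. Fndc3c1 had -1.24 ± 0.20 against DOM (adjusted p = 0.0168) and -1.12 ± 0.20 against SPRET (adjusted p = 0.0485). Its call against DOM was lost without HYBRID 10 (adjusted p = 0.137), 11 (0.083), 19 (0.106), 20 (0.0551) or DOM 18 (0.109), each leaving 1 gene in place of 2, whereas without DOM 15 there were 3. Its call against SPRET was lost with DESeq2 size factors (adjusted p = 0.0515), without a filter on low counts (0.0969) and with the yolk sac score as a covariate (0.0553). SPRET against DOM gave 2 genes without SPRET 12, SPRET 14 or DOM 16 and 3 without SPRET 7, and HYBRID against SPRET gave 5 without SPRET 14. Without the placentas high in yolk sac markers Gm14597 (adjusted p = 0.0803 against DOM, 0.109 against SPRET) and Fndc3c1 (0.206 and 0.384) did not pass, and 1, 2 and 1 genes were called (HYBRID against DOM, SPRET against DOM and HYBRID against SPRET). Kctd20 (-1.28, adjusted p = 0.327, but -1.78 and 0.00623 against DOM without those placentas) and Cyp17a1 (1.14 in SPRET against DOM, adjusted p = 0.354) did not pass. With litter as a block 4 genes were called in HYBRID against DOM and 2 in SPRET against DOM, and with DESeq2 11, 12 and 10 in the 3 interactions.

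Pregnancy-specific glycoproteins were lower in DOM males than females (median -0.58, adjusted p = 3.76e-06, but adjusted p = 0.466 with an estimated correlation). They were higher in HYBRID males (0.73, adjusted p = 1.97e-09, but adjusted p = 0.326 with an estimated correlation). Their interaction was 1.31 (adjusted p = 7.90e-15, but adjusted p = 0.128 with an estimated correlation). Spongiotrophoblast genes were higher in HYBRID males (median 0.55, adjusted p = 0.00012, but adjusted p = 0.243 with an estimated correlation). Their interaction against DOM was 0.87 (adjusted p = 9.74e-06, but adjusted p = 0.115 with an estimated correlation). Ceacam genes were higher in HYBRID males (0.69, adjusted p = 4.60e-05, but adjusted p = 0.326 with an estimated correlation), with an interaction of 1.15 (adjusted p = 7.51e-07, but adjusted p = 0.128 with an estimated correlation). Erythroid genes were lower in HYBRID males (-0.74, adjusted p = 3.12e-08, but adjusted p = 0.263 with an estimated correlation). Macrophage genes were lower in SPRET males (-0.76, adjusted p = 1.37e-05, but adjusted p = 0.927 with an estimated correlation). MHC class I genes were lower in DOM males (-0.28, adjusted p = 0.000759, but adjusted p = 0.466 with an estimated correlation). No single member was called over all genes. Adjusted over the list alone, 10 glycoproteins, 3 spongiotrophoblast and 7 Ceacam genes were called in the interaction, and 3 erythroid and 3 macrophage genes within HYBRID and SPRET. Beside these groups, yolk sac endoderm genes were lower in DOM males (-1.69, adjusted p = 4.36e-05, but adjusted p = 0.532 with an estimated correlation), though not without DOM 8 (adjusted p = 0.0823) or the placentas high in yolk sac markers (0.845).

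**Figure D4:**
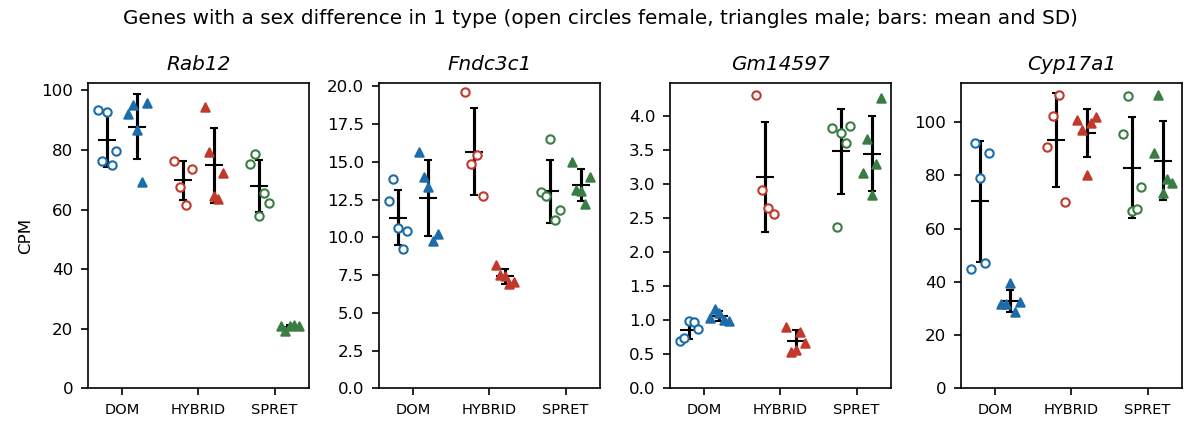
Expression in CPM (vertical axis) of Rab12, Fndc3c1, Gm14597 and Cyp17a1 by type, with 1 point per placenta (open circles female, triangles male) and bars for the mean and SD of each sex. Rab12 averaged 67.9 CPM in SPRET females and 20.7 CPM in SPRET males.

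In the MPA no gene was called between dams carrying hybrid and dams carrying domesticus litters with edgeR (0 of 18289), 666 genes had unadjusted p under 0.05, and DESeq2 called 1. The gene with the smallest p was Fmn1, a formin of the actin skeleton, with 20.2 CPM in DOM and 8.69 in DOMhl (n = 5 each, log2 -1.22 ± 0.17, adjusted p = 0.149), and without DOMhl 11 it was called (-1.41, adjusted p = 0.00147). The next were the astrocyte glutamate transporter Slc1a3 (-0.50 ± 0.11, adjusted p = 0.921), Ick (-0.39), the unnamed locus MSTRG.10249 (-1.64, 0.553 and 0.176 CPM) and Sacs (-1.19). Fmn1 was also called with DESeq2 (adjusted p = 1.88e-07), without a filter on low counts (0.0405) and without the dams of litters 11 and 20 (0.0111), each time as the only gene, and with all 15 dams in the fit 1 gene was called. The deposited test of the authors held 6 called genes, among them Fmn1 (-0.74, adjusted p = 1.59e-07) and the dopamine receptor Drd3 (-0.46, adjusted p = 0.00431). Here Drd3 stood at 11.2 and 6.74 CPM (-0.74 ± 0.25, adjusted p = 0.921). Genes of maternal behaviour were not called: oxytocin (Oxt) stood at 257 and 287 CPM (0.16), its receptor Oxtr at 15.4 and 14.1 (-0.13), Gal at 95.6 and 107.5 (0.17), the estrogen receptor Esr1 at 46.2 and 34.1 (-0.44), the progesterone receptor Pgr at 58.3 and 73.3 (0.33), Drd1 at 34.4 and 21.5 (-0.68) and Drd2 at 25.7 and 18.0 (-0.51). Prlr was not tested.

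As a group, striatal and septal neuron markers were lower in DOMhl (12 genes, median -0.50, adjusted p = 1.26e-07, but adjusted p = 0.809 with an estimated correlation), as were 24 immediate early genes, markers of recent neuronal activity (-0.28, adjusted p = 2.70e-05, but adjusted p = 0.868 with an estimated correlation). Ribosomal protein genes were higher (28 genes, 0.21, adjusted p = 2.70e-05, but adjusted p = 0.868 with an estimated correlation, and 0.439 without DOMhl 11). Interferon response genes were higher (27 genes, 0.20, adjusted p = 0.00626, but adjusted p = 0.868 with an estimated correlation), but not without DOM 8 (adjusted p = 0.0632), DOMhl 10 (0.0750) or DOMhl 11 (0.173). Heat shock genes were higher (18 genes, 0.18, adjusted p = 0.00752, but adjusted p = 0.868 with an estimated correlation), but not without DOM 8 (adjusted p = 0.0567) or DOMhl 11 (0.439). No set test passed for 39 maternal behaviour genes (median -0.06, adjusted p = 0.628), 24 dopamine and serotonin genes (-0.04, 0.398), 17 genes of the prolactin response (-0.05, 0.687), 18 of steroid signalling (0.06, 0.687) or 24 of GABA and glutamate signalling (-0.05, 0.700). Beside these groups the choroid plexus median was 1.00 (adjusted p = 0.145), and the list passed without DOMhl 9 (adjusted p = 0.00608), 10 (0.0140), 11 (0.0367), 19 (0.00800) or 20 (0.0129), in the other direction without 20. With the striatal and septal score as a covariate the immediate early genes (adjusted p = 0.954) and interferon response genes (0.106) did not pass.

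**Figure D5:**
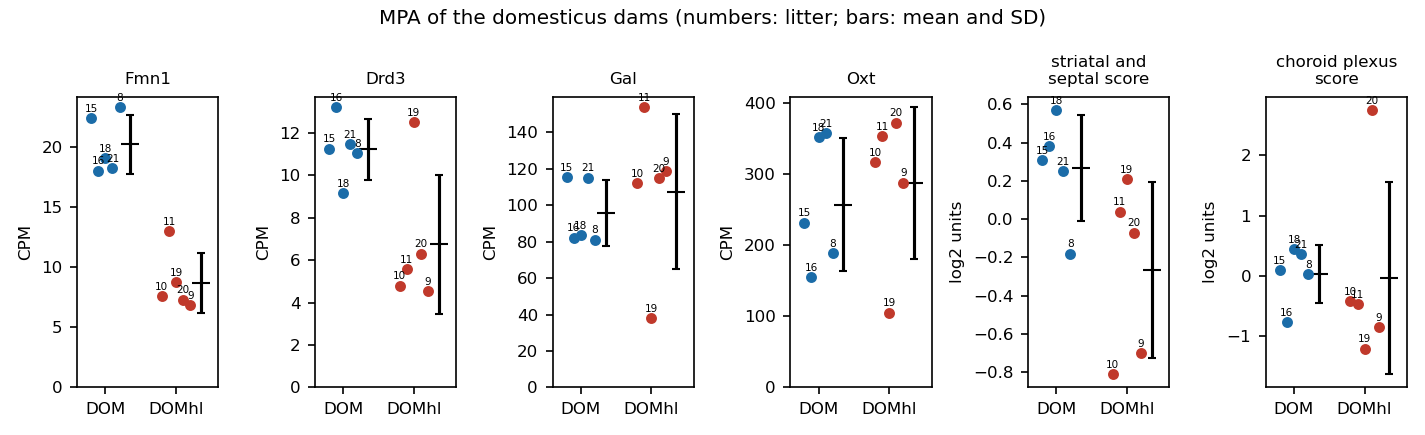
Expression in CPM of Fmn1, Drd3, Gal and Oxt, and marker scores in log2 units of striatal and septal neurons and of choroid plexus, in DOM and DOMhl dams, with 1 point per dam (numbers give the litter) and bars for the mean and SD. Fmn1 averaged 20.2 CPM in DOM and 8.69 in DOMhl.

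In the MPA the insulin-like growth factor Igf1 was lower in SPRET than in DOM dams (n = 5 each, 17.8 to 2.71 CPM, log2 -2.71 ± 0.25), as were Stat5a, a mediator of prolactin signals (-2.07 ± 0.16), Esr1 (50.8 to 19.2 CPM, -1.40 ± 0.40, adjusted p = 0.0123), Drd3 (-1.16 ± 0.32, adjusted p = 0.00922), Drd5 (-1.20), Slc6a3, the dopamine transporter (-1.50), Oprk1 (-1.25), Crhr2 (-1.52) and Oxtr (-0.48 ± 0.12, adjusted p = 0.0046). Tph2, the enzyme of serotonin synthesis, was higher (0.447 to 2.93 CPM, 2.71 ± 0.33), as were Galr2 (1.08), Npy5r (0.86) and Comt (0.90). Gal (-0.26, adjusted p = 0.525), Pgr (0.23), Drd1 (0.70, adjusted p = 0.303), Drd2 (0.08) and Oxt (-0.63, adjusted p = 0.246) were not called, although Oxt was without SPRET 13 (-1.30, adjusted p = 0.00387). Marker scores of neighbouring regions varied more among SPRET than among DOM dams. The cortical and hippocampal score ran from -0.64 to 1.35 in SPRET and from -0.29 to 0.05 in DOM. The striatal and septal score ran from -0.98 to 0.97 and from -0.37 to 0.42. Another extent of the dissected tissue is thus not excluded for regional genes such as Esr1 and Drd3.

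Maternal behaviour genes had 3 of 38 higher and 8 lower, dopamine and serotonin genes 6 of 23 higher and 5 lower, prolactin response genes 1 of 17 higher and 6 lower, GABA and glutamate genes 7 of 24 higher and 2 lower (Gabrg1 0.81, Slc32a1 -0.95, Grin2a -1.28) and steroid genes 2 of 17 higher and 2 lower, and none of these lists passed (adjusted p = 0.714, 0.546, 0.237, 0.714 and 0.811). Ribosomal protein genes had 13 of 24 higher and 3 lower, the only list that passed (median 0.42, adjusted p = 0.000351, but adjusted p = 0.998 with an estimated correlation). Counts of ribosomal protein genes may differ between the 2 annotations: Rps27 stood at 2.99 CPM in DOM and 234 in SPRET, and Rpl29 at 22.9 and 0. Heat shock genes gave 6 higher and 0 lower of 18, interferon response 4 and 5 of 27 (Mx1 3.62, Gbp3 2.14), MHC class I 1 and 4 of 11, cytokines 2 and 4 of 15 (Il33 1.77, Il18 -1.78), hypoxia 5 and 5 of 25, cholesterol synthesis 7 and 3 of 18, immediate early genes 1 and 2 of 24 and histones 0 and 2 of 4. Cell type markers gave 4 and 3 of 14 for astrocytes (Aqp4 0.99, Sox9 -1.39), 4 and 2 of 16 for microglia (Siglech -2.15), 0 and 3 of 18 for oligodendrocytes, 3 and 1 of 9 for their precursors (Bcas1 1.63), 2 and 5 of 13 for vascular cells (Acta2 -1.42), 2 and 3 of 13 for choroid plexus, none of 11 for ependyma, 0 and 2 of 3 for pituitary (Tshb -3.47) and 1 and 0 of 4 for blood. Neuron markers gave 1 and 3 of 10 for the preoptic area (Hmx3 -0.97), 2 and 0 of 11 for striatum and septum, 2 and 1 of 12 for thalamus, 2 and 1 of 12 for cortex and 2 and 1 of 11 for magnocellular neurons.

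Altogether 4934 of 14071 genes were called between SPRET and DOM dams, 2431 higher and 2503 lower in SPRET. All folds between SPRET and domesticus dams compare 2 annotations, including the largest, such as Btbd3 (0.123 to 266 CPM). SPRET against DOMhl dams gave 4688 genes, 2211 higher and 2477 lower in SPRET, with Igf1 (-2.78) and Stat5a (-2.01) lower again. Esr1 (-0.96, adjusted p = 0.0763) and Drd3 (adjusted p = 0.328) were not called there, Esr1 except without DOMhl 19 or SPRET 12.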

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

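The tests of the 3 patterns below were chosen after the results had been seen, and the predictions for yolk sac among the lower hybrid genes and for lost reads in the prolactin family were written after their values were known. The rearranged splits were planned.

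Of 25 placental prolactin genes 9 lay below both parents in HYBRID, and the set tests of the family were lost with an estimated correlation (adjusted p = 0.836 against DOM, 0.688 against SPRET). Loss of spretus reads on the domesticus reference could lower a hybrid only to the level of SPRET, but the median of the family against SPRET was -1.17. Its SE of 0.328 is a spread over the 25 genes taken as independent, not an error between libraries. The 9 members below both parents argue against this loss for those members. It stays open for members that fell against DOM but did not lie below SPRET, such as Prl3d1 (5.43 against SPRET) and Prl3b1 (0.41). A smaller junctional zone remains a candidate explanation. Outside the family, 20 markers of spongiotrophoblast and glycogen cells had a median of -0.42 against DOM, 0.52 of that of the family. Against SPRET their median was -0.46, 0.392 of that of the family. The bound of 0.5 set beforehand was met against DOM alone, so the test did not decide. These markers did not all fall: Phlda2 was called higher than both parents, and Igf2 and Gjb2 higher than DOM. Rhox9, Rhox6, Gjb3, Gyg and Cdkn1c were called higher than SPRET, and all other calls among the markers were lower. Yolk sac in the samples did not account for most of the 9 prolactin genes below both parents: 8 of the 9 genes stayed below both with the yolk sac score as a covariate. Without the placentas high in yolk sac markers 4 did, with wider errors per gene (median 0.358 in place of 0.282 against DOM). The family median was then -0.88 (before -0.81) against DOM and -1.35 against SPRET. The SE of these medians (0.303, before 0.274, and 0.319) is again a spread over genes taken as independent. Cell counts or in situ hybridization of the junctional zone would tell a smaller zone from lower expression per cell.

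Among genes lower in HYBRID than in DOM, loss of spretus reads might account for part. Hybrid males carry a domesticus X, and 5.69% of their X-linked genes against 10.2% of autosomal genes were called lower (ratio 0.559, Fisher exact two-sided p = 0.000251), which met the bound of at least 0.5 set beforehand for absence of this loss, but by less than the counting error of 0.099. Losing every spretus read lowers a gene by at most 1 log2 unit only if both alleles are equally expressed, which was not measured, so the 166 of the 2979 genes below that by more than 2 standard errors stay open too, although their share met the bound set beforehand. A difference in yolk sac score between the 2 types did not carry the group, since 2917 of the 2979 genes were still called lower with the score as a covariate. That score had similar means in DOM (0.62, SD 1.97) and HYBRID (0.76, SD 2.09), so the covariate could change this contrast little. Genes near 0 in SPRET placentas may be lost reads: 58 of 493 such genes could be tested in the MPA, counted on a spretus annotation, and there had a median log2 of -0.40.

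Striatal and septal markers were lower in the MPA of DOMhl dams with the preset correlation but not with an estimated correlation (adjusted p = 0.809), which could be another extent of the dissected tissue. The markers moved together within groups (median correlation of a member with the others 0.91), as a varying extent would give. Fmn1 kept its size with the marker score as a covariate (-1.11). Variation of the dissection toward other regions is not measured by this score, but the striatal and septal tissue it does measure did not account for Fmn1. The libraries of litters 11 and 20, high in stress and choroid plexus genes, could not account for the markers either, since their median was -0.58 without these dams.

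With group labels rearranged, chance could be excluded for the 3 pregnancy-type contrasts of placenta (HYBRID against DOM with its 2 types alone 6763 genes, highest other split 3181, HYBRID against SPRET 8859 and 3520, SPRET against DOM 11525 and 2115, 1 of 60 splits as large each, the highest others with 4 of the 5 litters of a type still together). For the SPRET dams, fits of only the dams compared gave 5334 genes and at most 1 in other splits against DOM. Against DOMhl they gave 3916 and 0 (1 of 60 each). A random assignment of dams could be excluded there. The 2 annotations followed the real split, so this test cannot tell species from annotation. For the genes outside both parents 980 were called and another split gave 1664 (2 of 60), and for the midparent 4736 and 6846 (2 of 60). The same split exceeded both real counts, and its hybrid group held 4 SPRET litters and 1 HYBRID litter. Both shares were under 0.05, the bound set beforehand, which speaks only to a random assignment of litters. Since a split that mixed the types gave more genes, the test cannot tell a hybrid outside its parents from other differences between types. For the interactions the real split had the most genes (HYBRID against DOM 1 gene and 0 elsewhere, SPRET against DOM 1 and 0, HYBRID against SPRET 3 and 1, with 1 of 60 each). These shares were under 0.05, but the other splits had a median of 0, so counts this small cannot exclude chance for a single gene. For the sexes the 16 splits that part as many littermate pairs are too few for a share under 0.05, so chance could not be excluded. DOM had 6 genes and at most 0 in the others (1 of 16), HYBRID 8 and 107 (2 of 16) and SPRET 7 and 0 (1 of 16). Splits that part fewer pairs gave at most 2, 5 and 25. In the domesticus dams the real split had 0 genes and the highest other 2, so that all 100 of 100 were as large whatever the data. By genes with unadjusted p under 0.05 the real split had 666 and 35 of 100 were as large (highest other 3492), so chance could not be excluded.

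Single libraries stood apart in 31 of 378 groups (8.2%), where chance gives about 5%. SPRET litter 6 held 6 pups. In the MPA, DOMhl 20 had a choroid plexus score of 2.75, DOMhl 19 an ependymal score of -0.85, Gal at 37.9 CPM and Oxt at 105 CPM, and DOMhl 11 a heat shock score of 0.43 and a hypoxia score of 0.21. DOM 21 had a heat shock score of 0.06, DOM 15 a vascular score of -0.42 and Esr1 at 56.6 CPM, DOM 8 had Drd2 at 17.9 CPM and DOM 16 had the unnamed locus MSTRG.10249 at 0.973 CPM. SPRET 13 had scores of -0.27 for dopamine and serotonin genes, -0.98 for striatal and septal neurons and -0.52 for vascular cells. In placenta, HYBRID 20 male had a cytokine score of 1.47, DOM 8 male an endoreduplication score of -0.33 and DOM 8 female a decidua score of 0.81 and a syncytiotrophoblast score of -0.42. HYBRID 9 female had a glycogen trophoblast score of 0.29, a maternally imprinted score of 0.70, H2-K1 at 269 CPM and Ngfr at 23.6 CPM. Other single values were Bdh2 at 16.4 CPM in SPRET 12 male, Nphs1 at 9.59 in HYBRID 19 female, H2-Q7 at 0.0986 in SPRET 6 female, Cyp21a1 at 0.0607 in SPRET 7 female, mt-Co2 at 64.8 and Alox12e at 0.353 in DOM 15 male, Triml1 at 0.0809 in SPRET 12 female and Rab12 at 19.3 in SPRET 13 male.

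The sex difference differed between types for Gm14597 (HYBRID against DOM -2.47, against SPRET -2.14), Fndc3c1 (-1.24 and -1.12) and Rab12 (SPRET against DOM -1.79, HYBRID against SPRET 1.82). Gm14597 and Fndc3c1 did not pass without the placentas high in yolk sac markers, and Fndc3c1 lost its call against DOM with single litters left out.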

How the results depend on the processing

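Counts of calls moved with fewer placentas, another test or a litter block. HYBRID against DOM gave 6475 genes with all placentas, 2652 with females alone, 3885 with males alone and 3801 without the placentas high in yolk sac markers, and HYBRID against SPRET 9007 and 4352 with females alone. The midparent contrast gave 4736, 1258 with females, 2986 with males and 2409 without the yolk-sac-rich placentas, and the genes outside both parents 980, 176, 582 and 466. The sexes of DOM differed in 36 genes with DESeq2 and 5 with litter as a block, those of HYBRID in 3 with the block and those of SPRET in 32 and 3. The interaction of HYBRID against DOM held 11 genes with DESeq2, 4 with the block and 1 without the yolk-sac-rich placentas, that of SPRET against DOM 12, 2 and 2, and that of HYBRID against SPRET 10 with DESeq2 and 1 without these placentas. The domesticus dams gave 1 gene with DESeq2, without a filter, with all 15 dams or without the dams of litters 11 and 20. With female embryos alone HYBRID minus SPRET placenta weight was -0.0101 g, and the share of embryo weight differed by -1.65 from DOM and -2.52 from SPRET. DESeq2 size factors, counts summed per litter, voom with litter as a random effect, counts divided by 4 and the yolk sac score as a covariate moved no count by over 1.5 times, but 21 of 399 named gene results lost their call with counts summed per litter and 29 of 403 with the random effect.

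With each litter left out in turn, counts ran from 5418 to 6654 for HYBRID against DOM, 8133 to 9240 for HYBRID against SPRET, 11631 to 12280 for SPRET against DOM, 691 to 1086 outside both parents and 3589 to 5030 for the midparent. They ran from 6 to 9, 7 to 10 and 6 to 17 for the sexes of DOM, HYBRID and SPRET, 1 to 3, 1 to 3 and 2 to 5 for the interactions (HYBRID against DOM, SPRET against DOM and HYBRID against SPRET), and 0 to 1, 4136 to 5479 and 4048 to 4711 for the dams. HYBRID minus DOM placenta weight ran from -0.0198 to -0.0155 g and SPRET minus DOM embryo weight from -0.133 to -0.0702 g, placenta weight from -0.00406 to -0.000348 g and share of embryo weight from 0.622 to 2.00.

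Of 443 list tests 94 passed, and 5 of these hold with an estimated correlation: Y-linked genes in the sexes of each type, and MHC class I and maternally expressed imprinted genes against the midparent. The midparent tests were on the log2 scale, and maternally expressed imprinted genes did not pass against DOM (camera adjusted p = 0.245) or SPRET (0.0645). Without the yolk-sac-rich placentas 65 of 87 passing tests still passed, and with the litter block 48 of 53. Direction turned, with camera adjusted p, for yolk sac endoderm in HYBRID males without HYBRID 11 (0.0317, with 2.03e-05 to 0.817 over litters), macrophages in HYBRID males with the litter block (0.0408, 0.112 to 0.810 over litters), interferon response in HYBRID males without the yolk-sac-rich placentas (0.00493, 0.0895 to 0.907), yolk sac endoderm in the interaction of HYBRID against DOM without them (9.80e-07, 4.07e-06 to 0.926) and choroid plexus in DOMhl dams without DOMhl 20 (0.0129, 0.00608 to 0.463). Log2 changes turned for Drd1 (-0.21) and Egr3 (-0.093) in SPRET against DOMhl dams with the striatal score as a covariate, for Ccl12 in females alone (-0.94 in HYBRID against SPRET, 0.51 in SPRET against DOM) and for Lum in males alone in SPRET against DOM (0.081). The cause was not tested.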

Other observations

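No explanation was tested in this part, and its groups come from the planned lists. Between the parents, SPRET placentas had 8 of 14 fetal endothelium genes lower and 1 higher, 9 of 14 macrophage genes lower and 1 higher (Lyve1 -4.76), 13 of 34 cell cycle genes higher and 4 lower and 16 of 31 interferon response genes higher and 9 lower (Mx1 4.69, Ifi44 -4.13), and none of these lists passed the set test. Maternally expressed imprinted genes had 10 of 27 lower and 5 higher, and steroid genes 9 of 19 lower and 6 higher. HYBRID against SPRET, 16 of 27 maternally expressed imprinted genes were higher and 3 lower (adjusted p = 0.0645), with Tfpi2 (3.43) and Tnfrsf23 (2.64) above and Gatm (-3.13) below, and nutrient transporters had 10 of 29 higher and 9 lower. In the MPA of SPRET against DOMhl dams, 7 of 38 maternal behaviour genes were higher and 10 lower, 6 of 13 choroid plexus genes lower and 5 of 11 striatal and septal genes higher (8 over the list alone), without a set test that passed, and striatal genes passed without SPRET 13 (adjusted p = 0.00756). Ribosomal protein genes had 10 of 24 higher and 3 lower (adjusted p = 0.0499, but adjusted p = 0.951 with an estimated correlation), a call lost without DOM 15, DOMhl 10, 19, 20 or 9, or SPRET 13 or 14 (adjusted p from 0.0577 to 0.295).

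In male against female placentas, further lists passed with the preset correlation. In HYBRID males glycogen trophoblast genes were lower (median -0.23, adjusted p = 0.00482, but adjusted p = 0.185 with an estimated correlation, 0.116 without HYBRID 9 and 0.502 without the placentas high in yolk sac markers), with an interaction against DOM of -0.32 (adjusted p = 0.00261, but adjusted p = 0.115 with an estimated correlation and 0.0867 without those placentas). In SPRET males mitochondrial genes were higher (0.44, adjusted p = 0.013, but adjusted p = 0.927 with an estimated correlation, 0.503 and 0.147 without SPRET 13 and SPRET 7, and 0.152 without those placentas), and in DOM males lymphoid genes were lower (-0.73, adjusted p = 0.0045, but adjusted p = 0.466 with an estimated correlation, and 0.240 without DOM 8). With litter as a block, prolactin family genes were also lower in DOM males (median -0.17, adjusted p = 0.000121) and higher in HYBRID males (0.45, adjusted p = 2.42e-07). Yolk sac genes were higher in SPRET males with the block (0.66, adjusted p = 3.17e-17), and 7 of 15 were called over the list alone. Other lists that passed only with the block were, in HYBRID males, cathepsins (adjusted p = 0.0443), macrophages (0.0408), MHC class I (0.0415), cell cycle (0.00075), angiogenic factors (0.0471) and heat shock (0.0253), in SPRET males cathepsins (0.0245), and in the interactions yolk sac (0.0366) and cell cycle (0.00174) for HYBRID against DOM, cell cycle (0.0153) for SPRET against DOM and stroma (0.0105) for HYBRID against SPRET. The block ended the calls of cytokines in HYBRID males (adjusted p = 0.893) and of nutrient transporters in the interaction of HYBRID against DOM (0.0695), and in that of HYBRID against SPRET those of yolk sac (0.0802), interferon response (0.445) and nutrient transporters (0.124). None of the lists that passed only with the block held with an estimated correlation (adjusted p from 0.227 to 0.712).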
